A study of Gallus gallus with 6 samples.

How the data were processed

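Messenger RNA of chicken hearts was profiled by RNA sequencing in 6 libraries. Per the labels, 3 libraries came from hearts of specific-pathogen-free chickens infected with fowl adenovirus 4 and sampled 48 hours after infection. The other 3 came from control hearts. The titles of the control libraries also carry the number 48, without a unit. The labels record total RNA extracted with a phenol-based reagent and an Illumina TruSeq type library kit, and the series design calls the product mRNA profiles. Each library took its group from its label, and no library was left without a group. The labels name no batch, sex or age, and do not say that the samples of a group came from separate birds. The p-values therefore measure the spread between these samples, which may be partly technical.

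The authors deposited gene counts for each library, whole numbers per Ensembl gene with no normalization applied, per the file headers and the values. Beside them the authors deposited FPKM values for the same libraries, per the file headers. For 10737 genes with at least 20 counts in every library, the count was divided by the FPKM value and by the library's own count total. The result, a gene length, was the same in all libraries, with a largest relative spread of 0.0041%. It was not compared with a gene length from another source. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.0 and the galGal5 build, without saying what each was used for. The counting tool, the annotation release, the strand setting and the filters are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies may share counts. No comparison of groups by the authors was used here. Every column of sample values was assigned to a sample by its name.

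The table holds 24881 genes, of which 12471 carry a gene name and 12410 only an Ensembl identifier. The unnamed genes hold 17.6% of all counts. The gene table supplied for this work (assembly GRCg7b) matched 0 of the identifiers, so unnamed genes stayed unnamed. In all, 6955 genes had no count in any library. Positions are those of the table (galGal5).

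Libraries held 11999371 to 19751916 counts. A single count corresponded to 0.0510 to 0.0894 CPM, the count scaled to a common library total. No pair of libraries within a group agreed within sampling noise, with a chi-square per gene from 18.1 to 55.2, and all 6 were kept. Separate preparations of the same sample could also exceed that noise, so the values do not show that the samples were separate.

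Genes were tested with edgeR 4.0.16 (R 4.3.3): the filter for expressed genes with its default minimum count of 10 and minimum total of 15, TMM factors, and the quasi-likelihood test of infected minus control with the group as the only term. This left 12762 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the test's F value. CPM values are given as mean ± SD over 3 libraries after TMM scaling. An exact permutation test of 3 against 3 libraries cannot give a 2-sided p below 0.1, so no single-gene permutation test is reported.

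Before the data were examined, 33 gene lists (pathways and cell type markers), the tests, the alternatives and the rule for naming genes were fixed. Of the lists, 32 had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the lists. The test was repeated with an estimated correlation and with fry, which asks whether the members of a list move on balance in 1 direction. Many list members have no gene of that name in the table, and lists were read from those that do. The named genes are, first, the 12 largest rises and 12 largest falls among called genes with a name, with no overlap between the groups and with at least 5 FPKM in the higher group. Second come up to 4 called members of each list with the largest change, or the 2 most abundant members where none was called. Last come NPPA, NPPB, MYH7, MYL2, ACTC1, IL6, IL1B, MX1, IFIT5 and HBAA where present. The rule took 127 genes, of which some are not reported here. The rule excludes no other name: further genes are said to be named after their values were seen. Of the last set, ACTC1, MYL2, IL6 and HBAA were tested under those names.

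The tests were run on simulated data for this comparison. Counts were drawn from the real means, library sizes and dispersions, with a known set of changed genes. That set held 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, and 12609 genes passed the filter there. In the real data 3310 of 12762 genes were called, a far larger share, and the adjusted threshold depends on that share. The percentages that follow describe the simulation, not what the real comparison recovers. With edgeR, 7.5% of the genes changed 1.5-fold, 53.7% of those changed 2-fold and 86.4% of those changed 4-fold were called in the right direction, and 11.7% of all calls were unchanged genes. In the same simulation, DESeq2 recovered 67.2% and limma voom 52.2% of the genes changed 2-fold, and unchanged genes made up 29.0% and 12.3% of their calls. In that simulation, where genes vary independently, camera called 0 of 30 lists of unchanged genes and fry 1 of 30, and each called 3 of 3 lists of raised genes.

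The alternatives tried were the replicate number as a block, leaving out each library in turn, no filter on low counts, at least 10 counts in every library, the size factors of DESeq2, library totals alone, the Wald test of DESeq2 1.42.0 and limma voom. Alternatives meant for a table without counts did not apply. After the data were seen, fits without the Z and W chromosomes and without mitochondrial DNA were added.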

Results

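Hearts of specific-pathogen-free chickens were compared 48 hours after infection with fowl adenovirus 4, a virus associated with fluid in the pericardial sac and with liver inflammation, with hearts of control chickens. Each group held 3 RNA-seq libraries. The control libraries held 14445706, 14833884 and 11999371 counts and the infected libraries 19751916, 13370746 and 18541511. Genes with at least 1 count numbered 15687 ± 244 in control and 15916 ± 132 in infected libraries (SD, n = 3). The first principal component of log2 CPM carried 66.3% of the variance and separated the groups, and the second carried 13.5% and set infected replicate 3 apart from the other 5 libraries. Infected replicate 3 also held 131 counts on the W chromosome, 0.00071% of its total, against 0.0296% to 0.0313% in the other 5 libraries.

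The comparison asked which transcripts differ between infected and control hearts. Infected hearts held far more transcripts of the antiviral interferon response and of antigen presentation, and more of most macrophage markers. They held fewer mitochondrial DNA mRNAs and fewer transcripts of red blood cell markers. Most members of these lists changed and the lists were called with a preset correlation between genes, but 0 lists were called with an estimated correlation. RSAD2, which encodes the antiviral enzyme viperin (ENSGALG00000016400, chromosome 3, 95406461 to 95415464, galGal5), went from 2.34 ± 1.32 to 1953 ± 127 CPM (SD, n = 3), an 828-fold rise. PIGY, a subunit of the enzyme that starts glycolipid anchor synthesis, went from 29.6 ± 2.14 to 1.15 ± 0.347 CPM, a 25.1-fold fall. Of 12762 genes tested with edgeR's quasi-likelihood test, 3310 changed at a Benjamini-Hochberg adjusted p under 0.05, with 1785 raised and 1525 lowered. At least 2-fold changes were called for 860 raised and 613 lowered genes, 1473 in all, and 898 of the 3310 genes carry no name in the table. The groups did not overlap in 5715 of the tested genes, 44.8%, where chance gives 10%. The counts depended on single libraries: 2083 genes changed (882 lowered) without infected replicate 1 and 2199 (962 lowered) without control replicate 1, while 971 and 992 were lowered without control replicates 2 and 3.

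Among the named genes the largest rise was that of RSAD2, with a log2 fold change of 9.69 ± 0.38 (SE). FAM26F, with 1 control count, came next at 8.13 ± 0.60. OASL, an oligoadenylate synthetase-like protein, followed at 8.05 ± 0.30, and CCL19, a chemokine for lymphocytes and dendritic cells, at 7.34 ± 0.33. EPSTI1 rose by 6.75 ± 0.16, the glycosyltransferase gene B3GNT7 by 6.47 ± 0.65 and TLR3, a receptor for double-stranded RNA, by 6.23 ± 0.19. ZNFX1, TRIM25, the RNA sensor IFIH1 and MOV10 rose by 5.66 ± 0.19, 5.39 ± 0.19, 5.31 ± 0.18 and 5.22 ± 0.12, and the mitochondrial carrier gene SLC25A47 by 5.11 ± 0.58. FAM26F had 1 count in the control libraries together and 469 in the infected libraries, a ratio of 365 with a 95% exact Clopper-Pearson interval of 65.3 to 14464 that covers counting error only. That 1 count lies in control replicate 3, so without this library no fold can be measured. B3GNT7 stood at 5.82 without control replicate 1. Among the largest falls, NR4A3 and NR4A1, orphan nuclear receptors among the immediate-early genes, stood at -3.97 ± 0.27 and -3.35 ± 0.31. FOSB, a subunit of the transcription factor AP-1, stood at -6.71 ± 1.85, with 1.38, 35.8 and 0.894 CPM in control replicates 1, 2 and 3. Its log2 fold change was -3.26 without control replicate 2, -7.57 without infected replicate 3 and -5.23 with limma voom. The adjusted p was 0.110 without infected replicate 1, 0.0897 without infected replicate 2 and 0.0673 without infected replicate 3, 0.157 with limma voom, and ran from 0.0249 to 0.157 over the alternatives that tested it. The membrane peptidase gene MMEL1 fell by 4.52 on the log2 scale (-5.44 without infected replicate 1), the vesicle fusion gene SNAP25 fell by 3.35, the matrix protein gene THBS2 fell by 3.25, the fibroblast protease gene FAP fell by 3.04 and the fatty acid binding protein gene FABP5 fell by 2.75. LY86 stood at -3.39 ± 0.22, KBTBD12 at -2.62 ± 0.31 and SEMA3G at -2.60 ± 0.23.

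**Figure D1:**
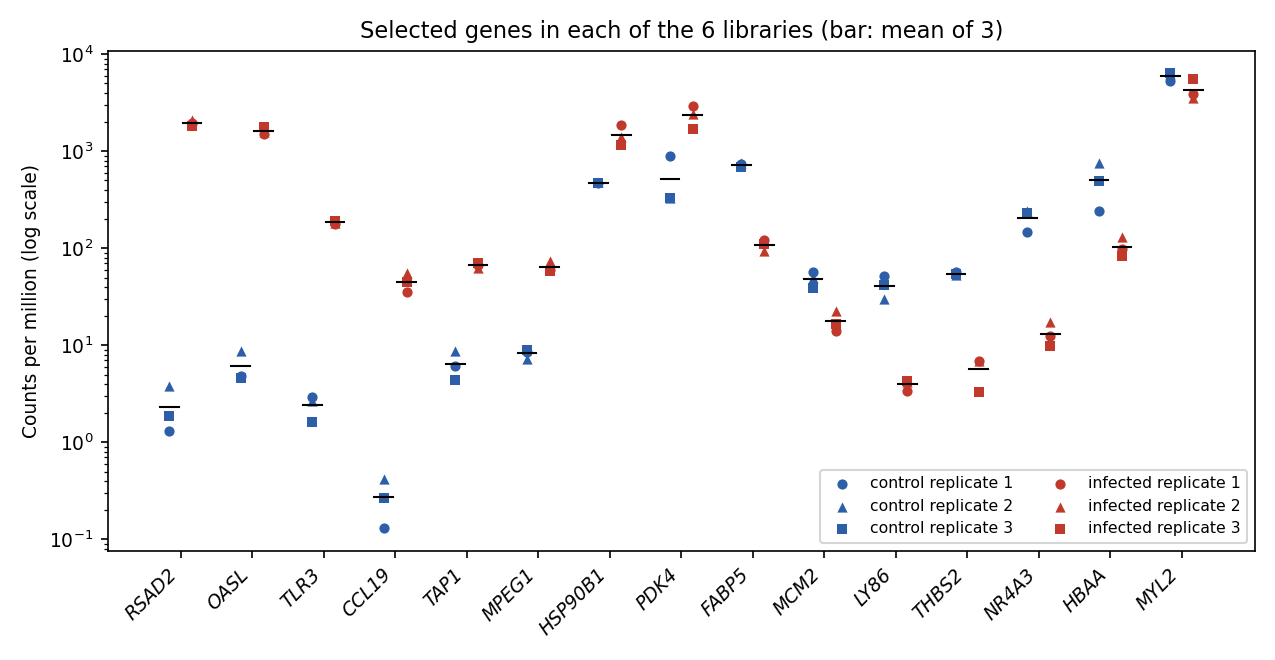
CPM (log scale) of 15 genes in each of the 6 libraries, with blue for control and red for infected hearts, a marker shape per replicate and a bar at the mean of 3. RSAD2 went from 2.34 ± 1.32 to 1953 ± 127 CPM, while MYL2, with 5951 ± 543 to 4324 ± 1059.9 CPM, was not called. A library with no count has no marker on the log scale.

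Of 33 gene lists fixed in advance, 32 could be tested with camera and 18 were called with the preset correlation, 10 up and 8 down. With an estimated correlation 0 lists were called at the adjusted threshold and 5 had an unadjusted p under 0.05, and with fry 14 were called. Fry did not call the lists of nuclear oxidative phosphorylation, the citric acid cycle, cell cycle, ribosomal proteins, extracellular matrix and lymphocytes, which camera called, and called those of adipocyte and atrial markers, which camera did not. Other divisions of the 6 libraries into 3 and 3 also gave 8 to 18 called lists with the preset correlation. Those divisions mix both conditions and keep part of the infection contrast, so they do not show what chance alone would give.

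Interferon-stimulated genes and sensors of viral nucleic acid rose nearly as a whole. Of 25 measured members 23 rose, 0 fell and 2 did not pass the test, with a median log2 fold change of 4.15, and 23 rose when adjusted over the list alone. RSAD2, OASL, EPSTI1 and TLR3 rose most, OASL from 6.10 ± 2.38 to 1622 ± 152 CPM. The list medians of infected replicates 1, 2 and 3 lay 4.04, 4.09 and 4.26 above the control mean. Camera gave an adjusted p of 4.94e-23, and adjusted p = 0.0507 with an estimated correlation.

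Antigen processing and presentation by the major histocompatibility complex rose in 14 of 17 members and fell in 0, with 15 raised when adjusted over the list alone and a median of 1.80. The aminopeptidase gene ERAP1, which trims peptides for class I molecules, rose by 4.15 ± 0.28. The peptide transporter genes TAP1 and TAP2 rose by 3.36 ± 0.22 and 2.86 ± 0.21, and NLRC5, a regulator of class I genes, by 3.07 ± 0.16. In camera the adjusted p was 4.13e-10, and adjusted p = 0.0507 with an estimated correlation.

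Cytokines, chemokines and their receptors rose in 15 of 25 members and fell in 0, with 16 raised when adjusted over the list alone. CCL19 went from 0.273 ± 0.143 to 45.1 ± 10.1 CPM, the chemokine gene CX3CL1 rose by 2.11 ± 0.31 and the receptor gene IL13RA1 by 1.96 ± 0.25. IL6, an inflammatory cytokine, stood at 3.10 ± 0.78 (0.161 ± 0.225 to 1.52 ± 0.623 CPM), or 5.06 without control replicate 2, where only 1 control count is left to set it, and its adjusted p was 0.0511 without infected replicate 2, 0.0868 without control replicate 1 and 0.0578 without control replicate 3, within 0.00309 to 0.0868 over the alternatives that tested it. The number of members raised was 8 without control replicate 3 and 9 without infected replicate 1. Camera gave this list an adjusted p of 4.07e-06, and adjusted p = 0.269 with an estimated correlation.

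Toll-like receptor and NF-kappaB signalling rose in 18 of 38 members and fell in 2, with 19 and 2 when adjusted over the list alone. The adaptor gene MYD88 went from 32.6 ± 2.47 to 223 ± 11.8 CPM, the kinase gene MAP3K8 rose by 3.25 ± 0.26 and SOCS3, a feedback inhibitor of cytokine signalling, by 2.93 ± 0.22. TNIP3 had 3 counts in the control libraries together and 69 in the infected libraries, a ratio of 17.9 (95% exact interval 5.88 to 89.0), and without control replicate 1 only 1 control count is left. The members that fell, NOS2 (-0.75) and TLR5 (-0.52), are named after their values were seen, and the number that fell was 1 without infected replicates 1 or 3 or control replicates 1, 2 or 3. TLR5 was not called without infected replicates 1 or 3 or control replicates 1, 2 or 3 (adjusted p up to 0.135 without infected replicate 1), nor with the replicate block (0.0930), no filter (0.0561) or library totals (0.109). The adjusted p in camera was 1.40e-07, and adjusted p = 0.0507 with an estimated correlation.

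Complement and acute-phase genes rose in 8 of 13 members and fell in 0, with 10 raised and 2 lowered when adjusted over the list alone. The complement protease gene C1S went from 16.7 ± 9.09 to 522 ± 173 CPM and SERPING1, which encodes its inhibitor, from 30.8 ± 3.77 to 227 ± 1.09 CPM. PTX3 rose by 3.66 ± 0.73 (4.79 without control replicate 1, 3.01 without infected replicate 2) and the receptor gene C3AR1 by 1.75 ± 0.34. Members that fell numbered 1 without infected replicate 2 or control replicate 3. Camera put the list at an adjusted p of 0.000519, and adjusted p = 0.564 with an estimated correlation.

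Macrophage markers rose in 12 of 16 members and fell in 1, with 13 and 1 when adjusted over the list alone. The pore-forming protein gene MPEG1 rose by 2.95 ± 0.14 and the scavenger receptor gene MARCO by 2.50 ± 0.56. LY86 instead went from 41.3 ± 10.6 to 3.95 ± 0.465 CPM. The fixed macrophage list shares CSF1R with the cytokine list, CTSS with antigen presentation and the C1Q genes with complement. It is therefore not independent of those lists, and whether the number of macrophages rose was not measured. Heterophils are the avian counterpart of neutrophils, and their markers rose in 4 of 5 members, also 4 when adjusted over the list alone, with NCF1 at 2.12 ± 0.34. NCF1 is also a member of the macrophage list, and CXCR1 and CSF3R, which rose too, are also members of the cytokine list. Only 5 of the 25 fixed members were tested, so a heterophil rise apart from those lists is not shown. The number of heterophil markers raised was 1 without control replicate 3 and 2 without infected replicate 1 or control replicate 2. Of 17 lymphocyte markers 6 rose and 1 fell, with 6 and 1 when adjusted over the list alone. GZMA, a protease of cytotoxic lymphocytes, rose by 3.22 ± 0.41 (3.82 without control replicate 1), and the number of lymphocyte markers raised was 2 without infected replicates 1 or 2 or control replicates 1 or 3. The marker that fell, EBF1 (-0.68), is named after its value was seen. EBF1 was not called without any 1 library (adjusted p up to 0.105 without control replicate 1), nor with library totals (0.0718). The macrophage, heterophil and lymphocyte lists had adjusted p values of 5.50e-06, 0.00818 and 0.0102 in camera, and adjusted p = 0.339, adjusted p = 0.269 and adjusted p = 0.564 with an estimated correlation.

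Markers of red blood cells, which are nucleated in birds, were lower in the infected hearts. Of 12 markers 8 fell and 0 rose, and 12 fell when adjusted over the list alone, with a mean log2 fold change of -1.77. The alpha globin gene HBAA went from 501 ± 259 to 104 ± 24.4 CPM. The carbonic anhydrase gene CA2, the membrane skeleton gene ANK1 and the linker histone gene H1F0 stood at -2.55 ± 0.31, -2.24 ± 0.25 and -2.16 ± 0.30. The list medians of control replicates 1, 2 and 3 were -0.61, 0.47 and 0.13 relative to the control mean, and those of the infected replicates -1.87, -1.44 and -2.06. Camera gave erythroid markers an adjusted p of 6.52e-06, and adjusted p = 0.483 with an estimated correlation.

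Heat-shock proteins and the unfolded-protein response rose in 19 of 41 members and fell in 3, with 24 and 3 when adjusted over the list alone. HSP90B1, a chaperone of the endoplasmic reticulum, went from 475 ± 8.02 to 1467 ± 350.0 CPM. The calcium-binding chaperone gene CALR rose by 1.80 ± 0.18, and the cytosolic chaperone genes HSPA2 and DNAJA4 by 1.77 ± 0.34 and 1.71 ± 0.30. HSP90AB1 (-1.34), DNAJB5 (-0.75) and HSF2 (-0.69), named after their values were seen, fell. DNAJB5 was not called without infected replicates 1 or 2 or control replicates 1, 2 or 3 (adjusted p up to 0.116 without control replicate 3). Genes of apoptosis and the p53 response rose in 17 of 36 members and fell in 4, with 18 and 4 when adjusted over the list alone. DRAM1, a p53 target in autophagy, rose by 4.13 ± 0.37 and the cell cycle inhibitor gene CDKN1A by 2.86 ± 0.32. The members that fell, named after their values were seen, were BIRC5 (-1.32), BOK (-0.65), CYCS (-0.60) and TP53INP1 (-0.55), and their number was 1 without infected replicates 1 or 2 or control replicate 2 and 2 without control replicates 1 or 3. BOK was not called without infected replicates 1, 2 or 3 or control replicates 1 or 2 (adjusted p up to 0.112 without control replicate 2), nor with library totals (0.0600). CYCS was not called without infected replicates 1 or 2 or control replicates 2 or 3 (adjusted p up to 0.0722 without control replicate 3). TP53INP1 was not called without infected replicates 1 or 2 or control replicates 1, 2 or 3 (adjusted p up to 0.116 without infected replicate 1), nor with the replicate block (0.0665). Camera gave the heat-shock and apoptosis lists adjusted p values of 7.61e-05 and 0.000717, and adjusted p = 0.483 and adjusted p = 0.322 with an estimated correlation.

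Of the 13 mRNAs encoded by mitochondrial DNA 9 fell and 0 rose, with 11 lowered when adjusted over the list alone and a median of -1.04. ND5, a subunit of complex I, went from 16975 ± 2269.7 to 5186 ± 344 CPM, and MT-CYB, the cytochrome b of complex III, from 23078 ± 3088 to 8544 ± 414 CPM. The longest unnamed genes of mitochondrial DNA, 976 bases at positions 1297 to 2272 and 1621 bases at 2346 to 3966, rose by 3.29 ± 0.36 and 2.87 ± 0.29. They lie ahead of ND1, where vertebrate mitochondrial DNA carries its ribosomal RNA genes. Of 15 shorter unnamed genes of mitochondrial DNA 8 rose and 1 fell, with the largest rises next to the long ones, 6.37 ± 0.22 at positions 1228 to 1296 and 4.68 ± 0.24 at 2273 to 2345. Together the long genes held 0.678 ± 0.155% of all counts in control and 6.27 ± 1.80% in infected libraries, and the rest of mitochondrial DNA, the shorter unnamed genes included, held 26.1 ± 1.98% and 14.1 ± 1.12% (SD, n = 3). The mitochondrial mRNAs had a camera adjusted p of 7.29e-07, and adjusted p = 0.483 with an estimated correlation.

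**Figure D2:**
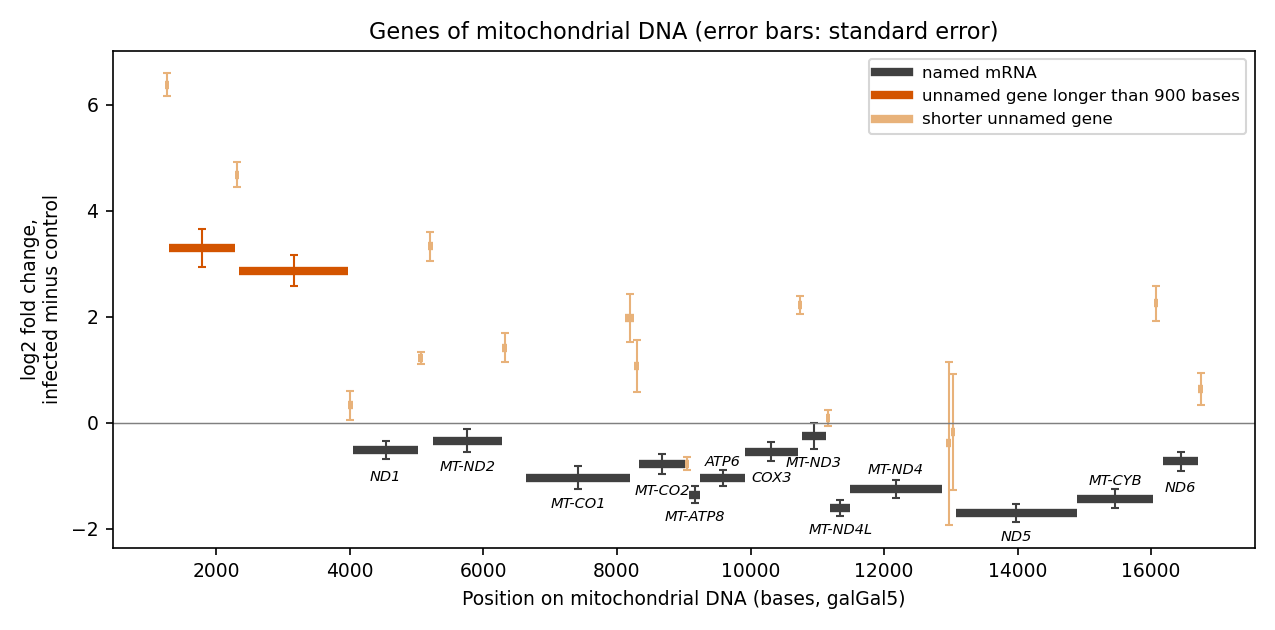
Log2 fold change (infected minus control, with standard error) of each tested gene of mitochondrial DNA against its position in bases (galGal5). The long unnamed genes before ND1 stand at 3.29 and 2.87, the shorter unnamed genes run from -0.78 to 6.37, and the 13 named mRNAs lie below 0, with ND5 at -1.71.

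Nuclear subunits of oxidative phosphorylation fell in 13 of 50 members and rose in 0, also 13 when adjusted over the list alone. The cytochrome c oxidase subunit gene COX7A2 fell by 0.80, and the complex I genes NDUFA8 and NDUFA6 stood at -0.73 ± 0.13 and -0.71 ± 0.12. The number that fell was 6 without infected replicate 1 or control replicate 3, 7 without control replicate 2, 8 without infected replicate 2 and 24 without infected replicate 3. Relative to the control mean, the list median was -0.11 in infected replicate 3 and -0.45 and -0.39 in infected replicates 1 and 2. Pyruvate dehydrogenase and the citric acid cycle fell in 7 of 20 members and rose in 0, with 8 lowered when adjusted over the list alone. The isocitrate dehydrogenase genes IDH3A and IDH3G stood at -1.33 ± 0.16 and -1.06 ± 0.15, and DLAT, a subunit of pyruvate dehydrogenase, at -0.81 ± 0.11. Members of this list that fell numbered 4 without infected replicates 1 or 2 or control replicate 3. For nuclear subunits and the citric acid cycle, camera gave adjusted p values of 4.09e-05 and 0.000583, and adjusted p = 0.664 and adjusted p = 0.639 with an estimated correlation.

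Fatty acid oxidation genes went both ways. Of 33 members 9 rose and 6 fell, with 10 and 6 when adjusted over the list alone. PDK4, a kinase that shuts off pyruvate dehydrogenase, went from 516 ± 324 to 2369 ± 629 CPM (log2 2.20, or 2.83 without control replicate 1), the acetyl-CoA carboxylase gene ACACB rose by 2.01 ± 0.13 and CPT1A, which admits fatty acids to mitochondria, by 1.34 ± 0.12. The list was not called (adjusted p of 0.686), with a median of -0.0033 against a mean of 0.16 and a camera direction of up. Glycolysis and hypoxia genes rose in 4 and fell in 3 of 34 members, with 4 and 3 when adjusted over the list alone. PFKFB3, P4HA2 and PFKP rose by 1.23 ± 0.18, 1.20 ± 0.18 and 0.79 ± 0.11, and the glucose transporter gene SLC2A1 fell by 0.79. KDM3A (0.32), which also rose, and GAPDH (-0.56) and EPAS1 (-0.64), which fell, are named after their values were seen, and the number that fell was 6 without infected replicate 3. KDM3A was not called without infected replicates 1 or 2 or control replicates 1, 2 or 3 (adjusted p up to 0.109 without control replicate 3), nor with the replicate block (0.0789), no filter (0.0585) or library totals (0.0561). GAPDH was not called without infected replicate 1 or control replicate 2 (adjusted p up to 0.0591 without infected replicate 1). That list had a median of -0.04, a mean of 0.0059 and a camera direction of down (adjusted p of 0.763).

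Lipid and sterol synthesis fell in 7 and rose in 1 of 24 members, with 7 and 1 when adjusted over the list alone. The regulator gene SREBF1 fell by 1.15, while the sterol isomerase gene EBP rose by 2.75 ± 0.41. The number that fell was 3 without infected replicate 1 or control replicate 1 and 4 without control replicates 2 or 3. With camera the adjusted p was 0.0144, and adjusted p = 0.564 with an estimated correlation.

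Most contractile genes of the heart were not called. Of 25 sarcomere members 3 rose, also 3 when adjusted over the list alone, and 0 fell. MYOM2 and NRAP, which tie the myosin and actin filaments to other structures, rose by 1.23 ± 0.12 and 1.00 ± 0.13. Cardiac actin ACTC1 stood at -0.47 ± 0.28 and the ventricular light chain MYL2 at -0.46 ± 0.20. Without infected replicate 3 they were called, ACTC1 at -0.83 (adjusted p of 0.0169, within 0.0169 to 0.476 over the alternatives that tested it) and MYL2 at -0.68 (0.0160, within 0.0160 to 0.309), and members that fell numbered 6 without infected replicate 3. MYL2 was also called with DESeq2 (adjusted p of 0.0493), which lowered 5 sarcomere members. The camera adjusted p of the sarcomere list was 0.802.

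Genes of calcium handling and ion channels rose in 3 and fell in 5 of 29 members, with 4 and 6 when adjusted over the list alone. KCNJ5, a potassium channel subunit of atrial cells, went from 2.06 ± 0.951 to 44.3 ± 9.40 CPM, and the gap junction genes GJA1 and GJC1 stood at 1.24 ± 0.16 and -0.55 ± 0.11. KCND3 stood at 1.12 ± 0.27, with an adjusted p of 0.0648 without infected replicate 1, 0.0581 without control replicate 2 and 0.0621 without control replicate 3, and within 0.00442 to 0.0648 over the alternatives that tested it. PLN (-0.36), SLC8A1 (-0.45), CAMK2D (-0.53) and CHRM2 (-0.40), named after their values were seen, also fell, and the number that fell was 1 without infected replicate 1 and 3 without infected replicate 2 or control replicates 2 or 3. PLN was not called without infected replicates 1 or 2 or control replicates 1, 2 or 3 (adjusted p up to 0.102 without infected replicate 1), nor with the replicate block (0.0713) or library totals (0.0553). SLC8A1 was not called without infected replicates 1 or 2 or control replicates 1, 2 or 3 (adjusted p up to 0.129 without control replicate 2), nor with the replicate block (0.0831), no filter (0.0574), the size factors of DESeq2 (0.0507) or mitochondrial DNA left out (0.0560). CAMK2D was not called without infected replicate 1 (adjusted p of 0.0527). CHRM2 was not called without infected replicate 1 (adjusted p of 0.0524). The list was not called (adjusted p of 0.964), with a median of -0.02, a mean of 0.15 and a camera direction of up.

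Genes of cardiac stress rose in 2 and fell in 2 of 12 members, with the same counts when adjusted over the list alone. NOX4, a source of reactive oxygen, fell by 2.04. ATF3 stood at -2.05 ± 0.52, or -1.14 without control replicate 2, with an adjusted p of 0.0745 without infected replicate 1, 0.0734 without infected replicate 2 and 0.0568 without infected replicate 3. RCAN1, at 0.89 ± 0.21, had 0.0688 without infected replicate 1, 0.0546 without infected replicate 2, 0.0650 without control replicate 2 and 0.0725 without control replicate 3, and TNC, at 1.87 ± 0.51 (2.53 without control replicate 1), had 0.0606 without infected replicate 1, 0.0876 without infected replicate 2, 0.0957 without control replicate 2 and 0.0797 without control replicate 3. Over the fits that leave out 1 library these values ran from 0.0117 to 0.0745, 0.00518 to 0.0725 and 0.0202 to 0.0957. The number that rose was 0 without infected replicates 1 or 2 or control replicates 2 or 3, and the number that fell 1 without infected replicates 1 or 2. The list median was 0.52 in infected replicate 3 and -0.50 and -0.43 in infected replicates 1 and 2, and camera gave an adjusted p of 0.830.

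Genes of DNA replication and mitosis fell in 16 of 48 members and rose in 0, with 18 lowered and 1 raised when adjusted over the list alone. MCM5 and MCM2, parts of the replicative helicase, fell by 1.96 and fell by 1.45, GINS1, a partner of that helicase, fell by 1.55 and the transcription factor gene E2F1 fell by 1.42. Relative to the control mean the list median was -0.84 and -0.84 in infected replicates 1 and 3 but 0.0056 in infected replicate 2, and the number that fell was 9 without infected replicate 1 or control replicate 1. Camera gave the cell cycle list an adjusted p of 9.07e-06, and adjusted p = 0.639 with an estimated correlation.

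Immediate-early genes fell in 10 and rose in 2 of 26 members, with 10 and 2 when adjusted over the list alone. NR4A3 went from 207 ± 51.1 to 13.2 ± 3.83 CPM and NR4A1 from 126 ± 21.8 to 12.4 ± 5.08 CPM. MYC (0.94) and KLF6 (0.79), named after their values were seen, rose. MYC was not called without infected replicate 1 (adjusted p of 0.0625). The number that fell was 3 without infected replicates 1 or 2 and 6 without infected replicate 3 and 5 with limma voom, and the number that rose 1 without infected replicate 1. The control libraries differed here, with list medians of -0.09, 0.79 and -0.68 for control replicates 1, 2 and 3. The list was not called (adjusted p of 0.0808), but it was without control replicate 3 (0.00507), with no filter (0.0494) and with library totals (0.0358), within 0.00507 to 0.815 over the alternatives that tested it.

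Cytosolic ribosomal proteins fell in 3 of 59 members, RPL5 (-0.50 ± 0.11), RPL10A (-0.40 ± 0.10) and RPL13 (-0.38 ± 0.11), and in 0 when adjusted over the list alone. The number that fell was 0 without infected replicate 1 or control replicates 2 or 3 and 6 without infected replicate 3. RPL5 had an adjusted p of 0.0618 without infected replicate 1, 0.0548 without control replicate 2 and 0.0574 without control replicate 3, and RPL10A and RPL13 had leave-one-out ranges of 0.0177 to 0.0812 and 0.0522 to 0.118, where RPL10A stayed called only without infected replicate 3 and RPL13 in 0 of the 6 fits. With the replicate block RPL10A and RPL13 had 0.0502 and 0.0687, and with library totals RPL13 had 0.0806. The list had a camera adjusted p of 0.00456, and adjusted p = 0.692 with an estimated correlation.

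Extracellular matrix genes fell in 10 and rose in 5 of 43 members, with 13 and 6 when adjusted over the list alone. THBS2 went from 54.4 ± 1.89 to 5.72 ± 2.10 CPM. THBS1 stood at -1.81 ± 0.44 and the collagen gene COL12A1 at 2.22 ± 0.62, with adjusted p values of 0.0588 without infected replicate 1 and 0.0546 without infected replicate 2 for THBS1 and 0.103 without infected replicate 1, 0.0907 without infected replicate 2, 0.0509 without control replicate 1, 0.0992 without control replicate 2 and 0.108 without control replicate 3 for COL12A1, and within 0.00972 to 0.0588 and 0.00229 to 0.108 over the alternatives that tested them. With limma voom COL12A1 had 0.108. THBS1 stood at -1.13 without control replicate 2. Beside COL12A1 and TNC, ADAMTS4 (1.54), SERPINH1 (1.24) and TGFB3 (0.40), named after their values were seen, rose. The number that fell was 6 without infected replicate 1, and the number that rose 2 without infected replicate 2 or control replicates 2 or 3 and 3 without infected replicate 1 or control replicate 1. TGFB3 was not called without infected replicates 2 or 3 or control replicates 1, 2 or 3 (adjusted p up to 0.0991 without control replicate 3), nor with the replicate block (0.0739). The list median was -0.77 in infected replicate 3 and -0.26 and -0.07 in infected replicates 1 and 2. The adjusted p of the list was 0.0262, 0.275 without infected replicate 3 and 0.0804 without control replicate 1, and adjusted p = 0.792 with an estimated correlation.

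Endothelial markers rose in 6 and fell in 5 of 19 members, with 8 and 6 when adjusted over the list alone. The apelin receptor gene APLNR fell by 3.68, the receptor gene TIE1 fell by 1.26 and EGFL7 fell by 1.02, while the lipid receptor gene S1PR1 rose by 0.95 ± 0.12. ESAM (-0.91) and KDR (-0.38), named after their values were seen, also fell. KDR was not called without infected replicates 2 or 3 or control replicates 1, 2 or 3 (adjusted p up to 0.140 without control replicate 2), nor with the replicate block (0.0872), no filter (0.0592), library totals (0.0805) or mitochondrial DNA left out (0.0505). Of 16 fibroblast markers 2 fell and 0 rose, with the same counts when adjusted over the list alone. FAP went from 37.9 ± 11.8 to 4.63 ± 0.993 CPM, and LUM stood at -0.65 ± 0.16, with an adjusted p of 0.0647 without infected replicate 2 and 0.0633 without control replicate 1, within 0.00168 to 0.0647 over the alternatives that tested it. The fibroblast median was -0.80 in infected replicate 3 and -0.01 and 0.39 in infected replicates 1 and 2. The number of fibroblast markers raised was 2 without infected replicate 3, and the number lowered 1 without control replicate 1. Of 15 smooth muscle and pericyte markers RGS5 (-1.04 ± 0.11) and CSPG4 (-0.74 ± 0.17) fell and 0 rose, with the same counts when adjusted over the list alone. CSPG4 had an adjusted p of 0.0516 without infected replicate 2, 0.0501 without control replicate 1 and 0.0577 without control replicate 2, within 0.00108 to 0.0577 over the alternatives that tested it, and the number of smooth muscle markers raised was 1 without infected replicate 2. These 3 lists were not called (adjusted p of 0.526, 0.448 and 0.763), and smooth muscle markers had a median of 0.04 and a mean of 0.0077 with a camera direction of down.

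Adipocyte markers rose in 3 and fell in 1 of 9 members, with 4 and 1 when adjusted over the list alone. The lipase gene PNPLA2 went from 84.8 ± 42.6 to 394 ± 145 CPM. The number that rose was 1 without infected replicate 1 or control replicates 1 or 3, and the number that fell 0 without infected replicates 1 or 2 or control replicates 1, 2 or 3. The adjusted p of the list was 0.0506. It was 0.0379 and 0.0450 without infected replicates 2 and 3, 0.0174 and 0.0363 without control replicates 2 and 3, 0.0258 with no filter, 0.0332 with the replicate block, 0.0496 with the size factors of DESeq2 and 0.00229 with fry, within 0.00229 to 0.349 over the alternatives that tested it.

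Atrial markers rose in 2 and fell in 1 of 9 members, with the same counts when adjusted over the list alone. Beside KCNJ5, the growth factor gene BMP10 rose by 2.69 ± 0.40 (3.40 without control replicate 1), and the transcription factor gene TBX3 fell by 1.42 (adjusted p of the list 0.308, and 0.0108 with fry). Of 8 ventricular markers 0 rose and 0 fell, also when adjusted over the list alone, with MYL3 at -0.43 ± 0.18. All 8 had a log2 fold change below 0, with a median of -0.30. DESeq2 called MYL3 (adjusted p of 0.0304, within 0.0304 to 0.320 over the alternatives that tested it) and lowered 2 ventricular markers. Without infected replicate 3 the ventricular list was called (0.0320, against 0.104 with all libraries and within 0.0320 to 0.664 over the alternatives that tested it), and the number that fell was 2 without infected replicate 3. Epicardial markers included TBX18, which rose by 1.36 ± 0.26, and the retinoic acid synthesis gene ALDH1A2, which fell by 1.87, as the calls among 9 members, with the same counts when adjusted over the list alone (adjusted p of the list 0.314). Among 5 skeletal muscle markers TNNT3 was called at 1.09 ± 0.32, with 1 raised and 1 lowered when adjusted over the list alone (adjusted p of the list 0.763). TNNT3 was not called without any 1 library, with 0.0557 without control replicate 2 as the lowest adjusted p, and it was not called with the replicate block, with no filter or with DESeq2. Of 3 hepatocyte markers, too few for the list test, APOA1, a lipoprotein component, went from 76.0 ± 29.6 to 462 ± 64.9 CPM, and 2 rose when adjusted over the list alone. The number of hepatocyte markers raised was 2 without control replicate 1.

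**Figure D3:**
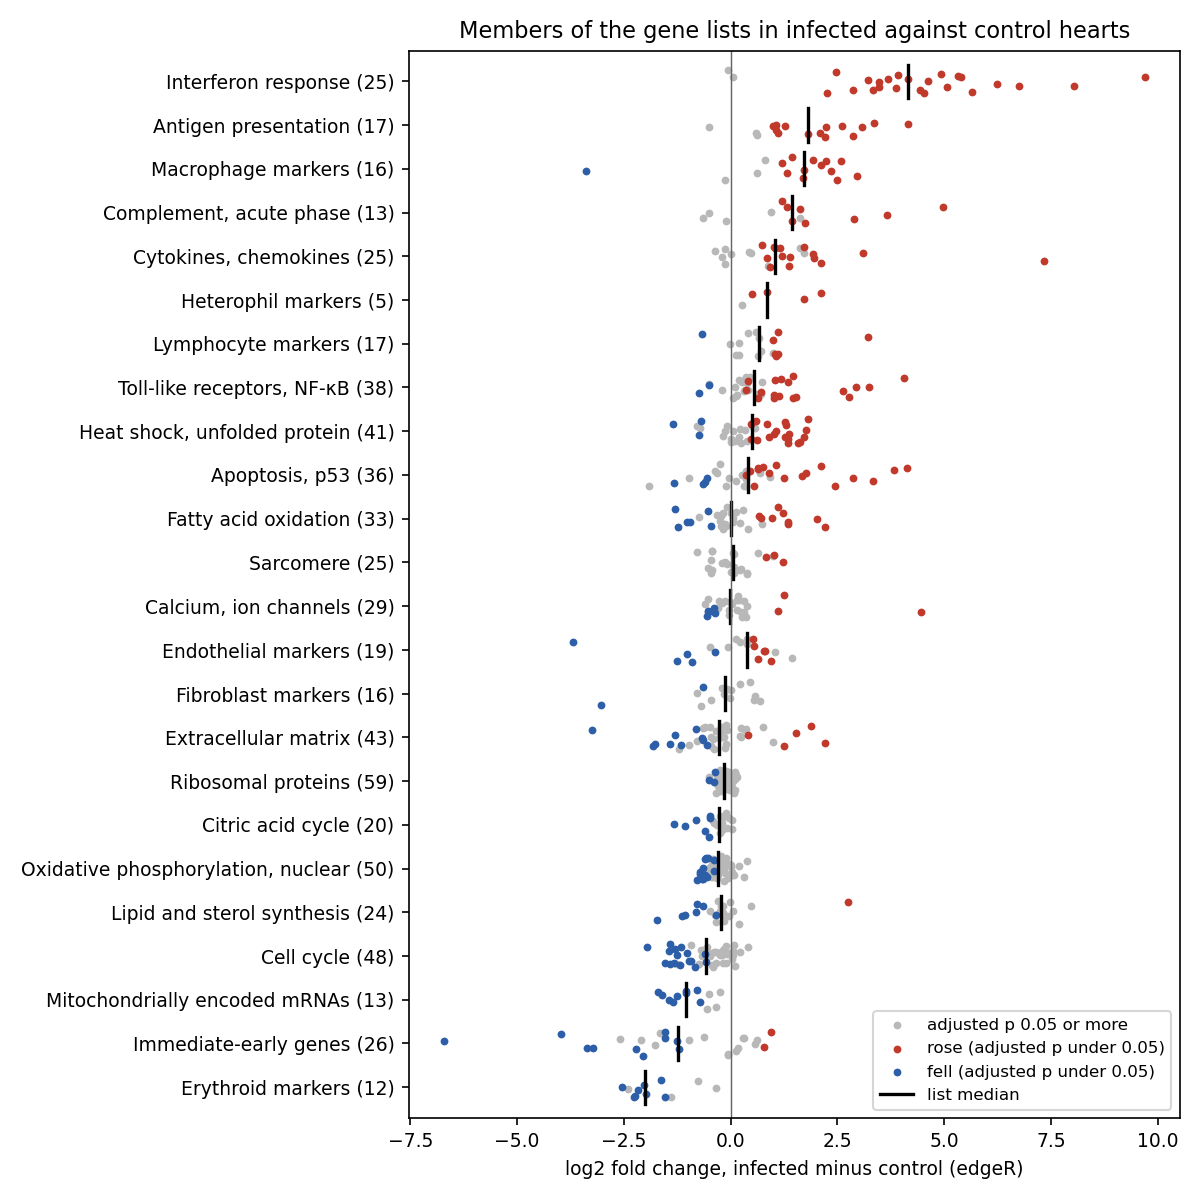
Log2 fold change (infected minus control) of every tested member of 24 gene lists, with red for members that rose, blue for members that fell, grey for the rest and a black bar at the list median. The interferon list has a median of 4.15 and the mitochondrial mRNAs a median of -1.04, and the number of tested members stands beside each name.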

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

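The fits without the Z and W chromosomes and without mitochondrial DNA were chosen after the data were seen. The numbers of genes changed, raised, lowered and changed at least 2-fold stayed within 1.5 times their values under every alternative but the loss of single libraries, and 0 of the called genes that an alternative tested turned direction (3000 of the 3310 with at least 10 counts in every library, 3189 without the Z and W chromosomes, 3280 without mitochondrial DNA and all 3310 elsewhere). With 1 library left out, 2083 to 3501 genes changed, 882 to 1579 were lowered, 1201 to 1922 were raised and 1208 to 1600 changed at least 2-fold. Fewer samples enter those fits. DESeq2 called 3598 genes, 3209 of them among the 3310, and limma voom 3267, with 3165 of them shared. Library totals alone gave 2998 genes with 60.7% raised, against 53.9%, and moved the median log2 fold change by 0.046. Leaving out the Z and W chromosomes gave 3286 genes and leaving out mitochondrial DNA 3298. The number of lists called was 0 with an estimated correlation in camera, against 18. For the Toll-like receptor list the estimate was 0.0101, near the preset 0.01, yet its adjusted p in camera went from 1.40e-07 to 0.0507. For heterophil markers the estimate was -0.054, below the preset, and that call was also lost. These values argue against a higher correlation between genes as the reason for those lists. Other lists had higher estimates, such as 0.85 for mitochondrial mRNAs. Since calls were lost at low and at high estimates, the loss of every call is not by itself a sign of correlation between genes. Its cause was not tested further. The direction of 6 lists that were not called reversed when a library was left out, and their adjusted p values over those fits ran from 0.423 to 0.998 for the sarcomere, 0.554 to 0.998 for calcium and ion channels, 0.466 to 0.992 for cardiac stress, 0.0864 to 0.974 for fibroblasts, 0.214 to 0.974 for smooth muscle and 0.513 to 0.988 for skeletal muscle. Of the 127 named genes, 104 to 119 kept their call status with 1 library left out, and 122 to 127 under the other tools and scalings.

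The replicate numbers in the titles gave no sign of pairing. The deviations of same-numbered libraries from their group means correlated at -0.10, -0.08 and 0.02 across genes. Those of differently numbered libraries correlated at -0.04 to 0.13. With 3 libraries per group these values cannot exclude pairing. With the replicate number as a block, 2432 genes changed (1347 raised, 1085 lowered, 1300 at least 2-fold) and 10 named genes lost their call. Depth limits low genes most: 3 counts correspond to 0.153 to 0.268 CPM.

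Counts of called list members also moved by more than 1.5 times outside the loss of single libraries. With the replicate block, members that fell numbered 1 for Toll-like receptors, 1 for complement, 3 for calcium, 1 for ribosomal proteins and 4 for lipids, and members that rose 2 for heterophils, 1 for adipocytes and 0 for skeletal muscle. Without a filter 1 Toll-like receptor member fell, 1 adipocyte marker rose and 0 skeletal muscle markers rose. With at least 10 counts in every library, where some members drop out, 1 cell cycle, 0 lipid, 2 heterophil, 0 skeletal muscle and 1 atrial member rose. With library totals 1 Toll-like receptor, 1 sarcomere, 4 lipid and 0 lymphocyte members fell. With DESeq2, 5 glycolysis, 5 sarcomere, 6 ribosomal, 2 epicardial, 2 ventricular and 1 skeletal muscle members fell, and 1 cell cycle, 2 hepatocyte and 0 skeletal muscle members rose. With limma voom 5 immediate-early members and 1 sarcomere member fell and 2 hepatocyte markers rose.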

Other observations

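The tests of gene families, mitochondrial genes, sex chromosomes and erythroid markers were chosen after the results were seen, and what the other divisions of the libraries would show was also written down after. Gene families were read from shared letters in the gene symbols, and some overlap the fixed lists. Of 133 families with at least 8 tested members, 7 were called by camera with the preset correlation and 0 with an estimated correlation. Interferon regulatory factors (IRF) rose in 6 of 8 members, interleukins and their receptors (IL) in 13 of 22, caspases (CASP) in 5 of 8, DDX helicases in 6 of 20, ZCCHC zinc finger genes in 4 of 10 and genes named CD in 7 of 22, with 0 falling in each. Genes with RPL symbols, the only called family that was lower, fell in 6 of 36 members and rose in 0 (adjusted p of 0.0498, shared by the CD, DDX, CASP and ZCCHC families). This family takes in genes outside the fixed list of ribosomal proteins, where 3 of 59 members fell. Among families not called, MCM helicase genes fell in 5 of 8 members with a median of -0.76 (adjusted p of 0.115), and collagens fell in 8 and rose in 3 of 24 (adjusted p of 0.148).

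Genes without a name in the table include some of the largest rises. Chosen after their values were seen, ENSGALG00000016142 on chromosome 1 went from 0.603 ± 0.239 to 528 ± 130.1 CPM (SD, n = 3) and ENSGALG00000045085 on chromosome 6 from 6.93 ± 1.95 to 4509.7 ± 404 CPM. Histone cluster genes HIST1H2B5 and HIST1H4H, also chosen after their values were seen, rose by 2.45 ± 0.30 and 1.70 ± 0.32 on the log2 scale.

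The real division of the 6 libraries gave 3310 changed genes, and the highest of the other divisions 0 with edgeR, the only tool run on them. Each other division mixes infected and control libraries in both of its groups, so the infection difference widens the spread within them. A count of 0 was therefore likely beforehand and decides nothing. These divisions also keep part of the infection contrast, and the interferon list was called in 9 of them. For at least 2-fold changes these were 1473 and 0, and for called lists 18 and 18. At an unadjusted p under 0.05 the real division gave 5030 genes and the others 112 to 431. For each gene count 1 of the 10 divisions gave a result as large, and for lists 2 of 10, and 10 divisions are too few for a share under 0.05. Camera p values of the interferon list, unadjusted, were 1.55e-24 in the real division and 4.60e-05 at the smallest in the others. The called lists of cytokines, Toll-like receptors, antigen presentation, heat shock, apoptosis and macrophages also had their smallest p in the real division. Every other called list had a smaller p in another division. For the cell cycle list another division gave 1.96e-33 against 2.27e-06. For mitochondrial mRNAs it was 1.06e-09 against 9.12e-08, and for erythroid markers 1.21e-10 against 1.43e-06.

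The unnamed mitochondrial genes at the positions of the ribosomal RNAs rose by 3.29 and 2.87 while mitochondrial mRNAs fell with a median of -1.04. On library totals, the larger share of those 2 genes would move every other gene by a log2 value of -0.084. On that scale the rest of mitochondrial DNA went from 26.1% to 14.1% of all counts, a far larger fall. These shares argue against the counts taken by those 2 genes as the whole cause. The median of -1.04 comes after TMM scaling and cannot be set against -0.084 directly. A higher amount of RNA without poly(A) tails in the infected libraries cannot be told apart from a change in the heart. Among them, 18 small nuclear and nucleolar RNAs had a median of -0.099 with 0 called. In contrast, 3 of 4 histone cluster genes and 8 of 15 shorter unnamed mitochondrial genes rose. The 18 RNAs had control means of only 0.539 to 4.39 CPM and the histone cluster genes 0.490 to 3.92 CPM. Both classes therefore rest on few counts. A candidate explanation on the biological side is a loss of mRNA that grows with distance from the ribosomal genes: start position and log2 fold change of the 12 mRNAs of the same strand correlated across genes at a Spearman rho of -0.64 and a Pearson r of -0.62 (permutation p of 0.028, adjusted for 2 relations 0.056; genes are not independent replicates). That misses the threshold, the correlation was weaker over all 13 mRNAs with the 1 of the other strand included (rho of -0.48 and r of -0.44, with a permutation p above 0.05), and gene length over the 12 gave a rho of -0.15 (permutation p of 0.629).

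Infected replicate 3 may come from a bird of the other sex. In chickens females carry Z and W and males a pair of Z chromosomes, and its W-linked share was 0.00071% against at least 0.0296% elsewhere, while its 570 Z-linked genes lay 0.49 above the other 5 libraries on the log2 scale, relative to autosomal genes, against -0.13 to -0.07 for the others. Whether the Z and W genes alone set it apart cannot be told: with autosomal genes only, the second component carried 9.36% of the variance and still placed it at an end, with infected replicate 2 at the other. Sex and the response of single birds stay open, and CCL19, ERAP1 and GZMA lie on the Z chromosome.

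Erythroid transcripts fell, and less blood in the infected samples cannot be told apart from fewer red cells in infected birds. All 12 erythroid markers had a log2 fold change below 0, from -2.55 to -0.33, but this count restates the fall that prompted it and decides nothing. The globins HBAA and HBAD, the latter named after its value was seen, together went from 0.0638% to 0.0139% of CPM. The smallest change was in SPTB, named after its value was seen. Both explanations stay open.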
